A study of Mus musculus with 6 samples.

How the data were processed

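Wild-type mouse 1-cell embryos were cultured with DMSO, CBR-5884 or CBR-5884 and S-adenosylmethionine, with 2 biological replicates per group per the labels. cDNA was made with the SMART-Seq v4 ultra-low-input kit and libraries with Nextera XT, per the labels' protocols. The protocols describe no strand marking and no molecular identifiers.

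The deposited table gave 1 signal value per gene and library, on an abundance scale that divides by transcript length. The submitters' processing notes name fastp, kallisto, DESeq2 and the build mm10, with no versions, roles or settings. The values resemble the TPM that kallisto writes, but the columns summed to 956209 in DMSO replicate 2 and up to 1059424 in CBR+SAM replicate 2, so each library had been scaled once more by a step not given in the sources used here. Rows carried Ensembl identifiers, and 35768 of 36065 were matched to a symbol in GENCODE M21, whose coordinates are those of mm10. They comprised 21785 protein-coding genes, 13489 pseudogenes, 546 others and 245 absent from M21. With so many pseudogenes in the index, reads of ribosomal protein genes, mitochondrial genes and other genes with near-identical copies may have been divided among records, and their values are uncertain for that reason. A symbol carried by several records was kept for the record with the highest mean. Obox4 matched no symbol and was not analysed here.

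Read counts were not used here. For protein-coding genes with a single transcript of more than 1500 bases, the low values fell on steps, and 75.9% to 80.8% of values of up to 10 reads lay within 0.1 of a whole number, against 20.0% by chance. This gave the estimated depth of each library, 21 to 27.0 M reads, but no whole counts for most genes, so the planned count test was replaced by the one fixed for normalized values. The step was searched in a range of less than a doubling, the same for all libraries, which held the estimates close together beforehand. The share on whole numbers cannot tell this depth from a lower one with a larger step. The 20.0% holds for a fixed step, whereas step and fragment length were chosen for the best fit. Values were transformed as log2(value + 1), and genes with a value of at least 1 in at least 2 libraries were tested, 12249 in all. A log2 change on this scale understates the change of low genes. The 3 groups were fitted together with limma 3.58.1 in R 4.3.3, with a mean-variance trend and 3 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05. The p-values measure the spread between these libraries. A permutation of 2 against 2 libraries cannot go below a two-sided p of 0.333 and was not used.

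Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 between genes, beside the same test with an estimated correlation, and adjusted over the 28 lists with a tested member. Lists were drawn for serine, folate and methionine metabolism, chromatin and DNA enzymes, genome activation, oocyte genes, stress, energy metabolism, the cell cycle, and cells that could accompany embryos. Genes were named by a rule fixed at the same time: up to 10 called genes per direction with a mean of at least 10, or otherwise the 5 with the smallest unadjusted p, all with groups that did not overlap, together with a fixed set of pathway genes and members of each list with the smallest p. Predicted genes were to be counted and not named, and those named are stated as chosen afterwards.

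Chance relations between comparisons that share libraries were simulated from the fitted model without effects, with 100 draws for correlations, all libraries or 1 left out, and 50 for opposite changes, and with the same variance for all libraries of a gene. The test was checked on simulated data for CBR against DMSO, with 200 changed genes among 12249 in each of 20 draws. It recovered 22.4% of genes changed 2-fold, 33.2% of those with a mean of at least 10, and 70.3% and 82.3% of genes changed 4-fold, with 4.25 false calls per draw. The changes were added to log2(value + 1), so the values of low genes changed by more than the stated fold. These rates apply to data with that many changed genes and that spread. Draws without effect from the same means and SDs gave CBR against DMSO changes with a variance of 0.106 across genes, against 0.0646 observed. A shift of 0.2 log2 in a list of 30 genes was found in 100% of draws, and an unshifted list in 5% (camera, unadjusted p under 0.05). The simulated genes varied independently of each other, whereas estimated correlations in the tested lists ran up to 0.911. The check therefore does not show how often a list of genes that vary together passes by chance. Near-identical copies were searched in the M21 transcripts with blastn 2.17.0.

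Alternatives were other scalings, filters and pseudocounts, a replicate block, precision weights, protein-coding genes alone, removal of a transcript length trend, the compared groups alone and each library left out in turn. Replicate numbers are shared by the groups, but the labels do not say that a number marks a shared batch, so they were not used as pairs.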

Results

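RNA was sequenced from wild-type mouse 1-cell embryos kept in culture with 1 of 3 additions: DMSO, the solvent control, CBR-5884, a small-molecule inhibitor of serine metabolism, or CBR-5884 together with S-adenosylmethionine (SAM), the methyl donor used by histone and DNA methyltransferases. The groups are named DMSO, CBR and CBR+SAM, and each had 2 biological replicates, which makes 6 libraries. The table held 36065 genes, of which 11529 to 11873 per library had a value of at least 1. Depth was not given with the values. From the steps between the lowest values of genes with a single transcript it was estimated at 26.3 and 21 M reads for DMSO replicates 1 and 2, 23.5 and 26.9 M for CBR, and 25.8 and 27.0 M for CBR+SAM. The steps were sought in a narrow range, so these depths and the read numbers drawn from them are approximate.

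The transcriptomes were those of early embryos that still carry the oocyte's mRNA. The most abundant transcripts were the oocyte gene Omt2b, with a mean of 16090 over the 6 libraries, Dppa3 with 14790, the mitochondrial gene mt-Atp6 with 12350, and Pttg1 (securin) with 12240. Btg4, which triggers the removal of maternal mRNA, averaged 5978. Genes listed for other cells that could accompany the embryos were low, except for Serpine2 of the cumulus cell list, which stood at 524 and 496 with DMSO, 567 and 568 with CBR, and 602 and 224.5 with CBR+SAM. Of the 30 genes of that list 4 were high enough to test. Serpine2 made up most of the list's sum, for example 524 of 540.6 in DMSO replicate 1, so its level alone does not show cumulus cells. The aromatase gene Cyp19a1 of cumulus cells lay between 8.14 and 13.6, the sperm protamine gene Prm2 between 9.86 and 14.7, and the summed blood cell genes between 0.101 and 1.53.

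Differences between the groups were small beside those between replicates. Across genes, the log2 values correlated at 0.971 to 0.985 within a group, at 0.976 to 0.989 between libraries of different groups with the same replicate number, and at 0.973 to 0.986 between the remaining pairs. The first principal component of the 500 most variable genes, with 42.0% of their variance, had replicate 1 of every group at -11.5 to -12.2 and the 3 second replicates at 4.55, 9.65 and 21.4. CBR+SAM replicate 2 lay furthest out, and the SD of the log2 difference between replicates, over the genes with a mean of at least 10, was 0.54 in CBR+SAM against 0.35 in DMSO and 0.34 in CBR.

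The comparison of CBR with DMSO asked what blocking serine metabolism does to the embryo's transcripts. Gadd45g, a stress-inducible gene with a reported link to active DNA demethylation, stood at 7.15 ± 0.732 in DMSO embryos and at 0.97 ± 0.289 in CBR embryos (mean ± SD, n = 2). Its relative Gadd45b stood at 1.24 ± 0.0436 and 0.416 ± 0.15. Ehmt2, which encodes the H3K9 methyltransferase G9a, stood at 1.56 ± 0.187 and 3.83 ± 0.303 in the same groups. None of the 12249 genes tested passed the adjusted threshold, and 98.8% of the 5939 genes with a mean of at least 10 had fitted changes within 0.5 on the log2 scale.

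Gadd45g (ENSMUSG00000021453) lies on chromosome 13 at 51846678 to 51848468 of mm10. Its log2 change was -2.05 (SE 0.21, 95% interval -2.55 to -1.56), with adjusted p = 0.253 by limma with Benjamini-Hochberg adjustment over all genes, and 0.000476 adjusted over the list alone, that of the 23 DNA methylation and demethylation genes. Both CBR libraries lay below both DMSO libraries, at 1.17 and 0.766 against 6.63 and 7.67. Ehmt2 (ENSMUSG00000013787, chromosome 17 at 34898469 to 34914052) had a log2 change of 0.91 (SE 0.19), with an adjusted p of 1 by limma and 0.0852 adjusted over the list alone, that of the 41 histone methyltransferase genes tested. The arginine methyltransferase gene Prmt5 followed in that list, at 3.05 ± 0.418 with DMSO and 4.95 ± 0.903 with CBR.

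**Figure D1:**
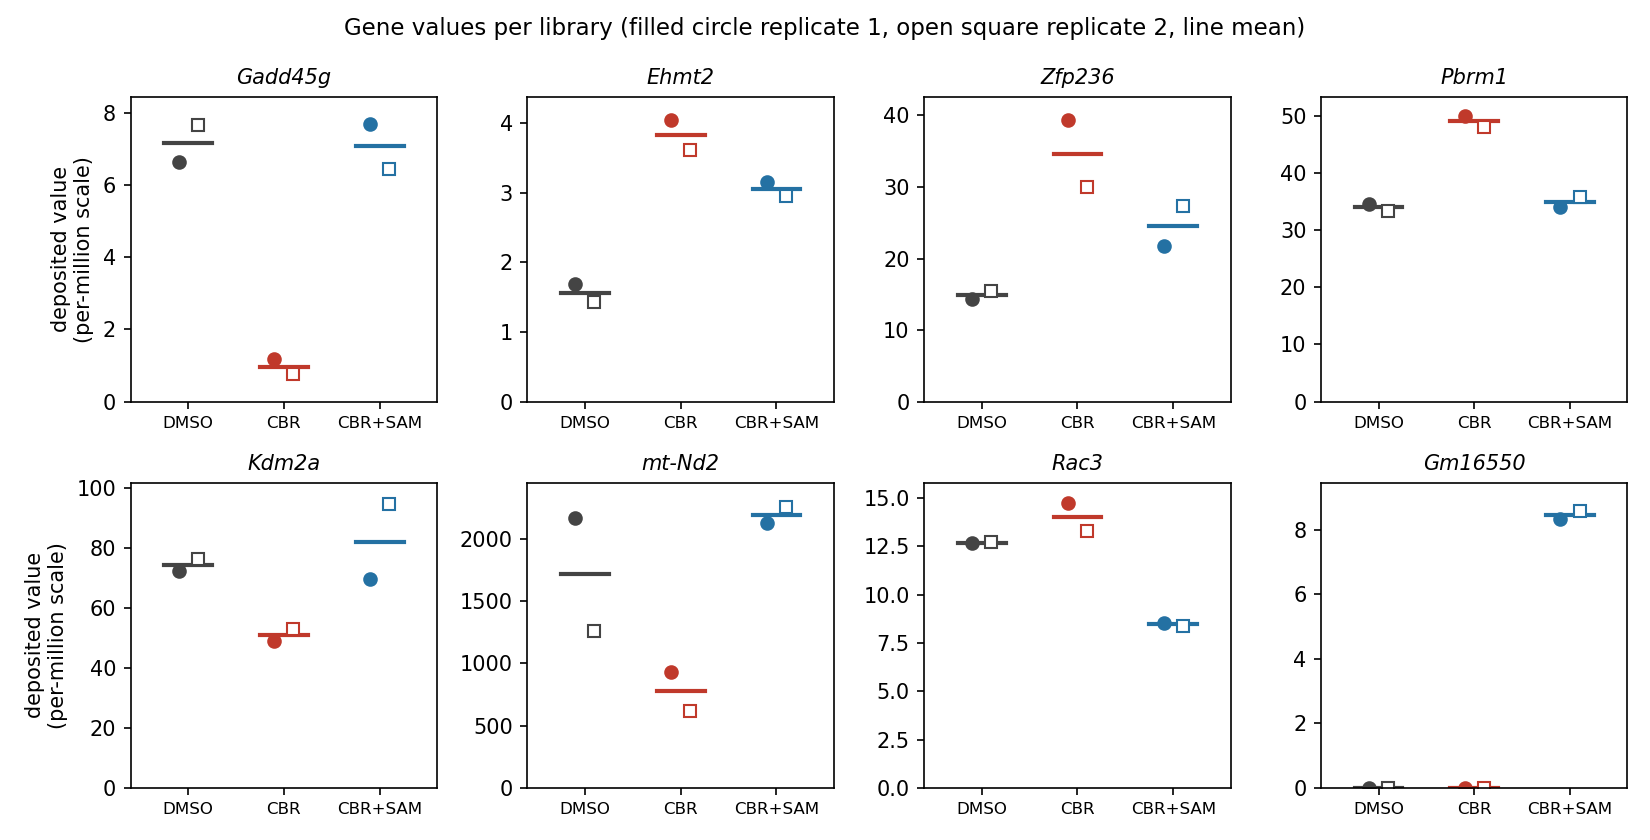
Deposited values of 8 genes on a linear scale, with 1 point per library and a line at the mean of each group's 2 libraries. Gadd45g lay at 1.17 and 0.766 in the CBR libraries and between 6.45 and 7.7 in the 4 others, and Gm16550 was at 8.34 and 8.59 in the CBR+SAM libraries and at or near 0 elsewhere.

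The genes of the blocked pathway stood at low to moderate levels and showed no difference beyond their error. Phgdh, the enzyme that commits glucose carbon to serine and the target CBR-5884 is known for, stood at 5.15 ± 1.14 with DMSO and 4.55 ± 0.376 with CBR, a log2 change of -0.14 (95% interval -0.68 to 0.41). Psph had a log2 change of -0.17 (-0.66 to 0.32), Shmt2 one of 0.22 (-0.18 to 0.61), and the mitochondrial folate enzyme Mthfd2 one of 0.13 (-0.22 to 0.47). Mat2a, which makes SAM from methionine, stood at 46.0 ± 0.685 and 42.7 ± 6.4. Shmt1 differed between replicates of every group, for example 8.48 and 3.07 with DMSO, and its interval ran from -1.18 to 1.85. Psat1 stayed at or below 0.258 and Ahcy at or below 0.631 in every library, too low to be tested. Of the 16 serine and glycine genes tested 11 had lower means with CBR (list adjusted p = 0.427, camera), and the 16 folate genes (0.706) and the 22 genes of the methionine and SAM cycle (0.976) were likewise not past the threshold.

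**Figure D2:**
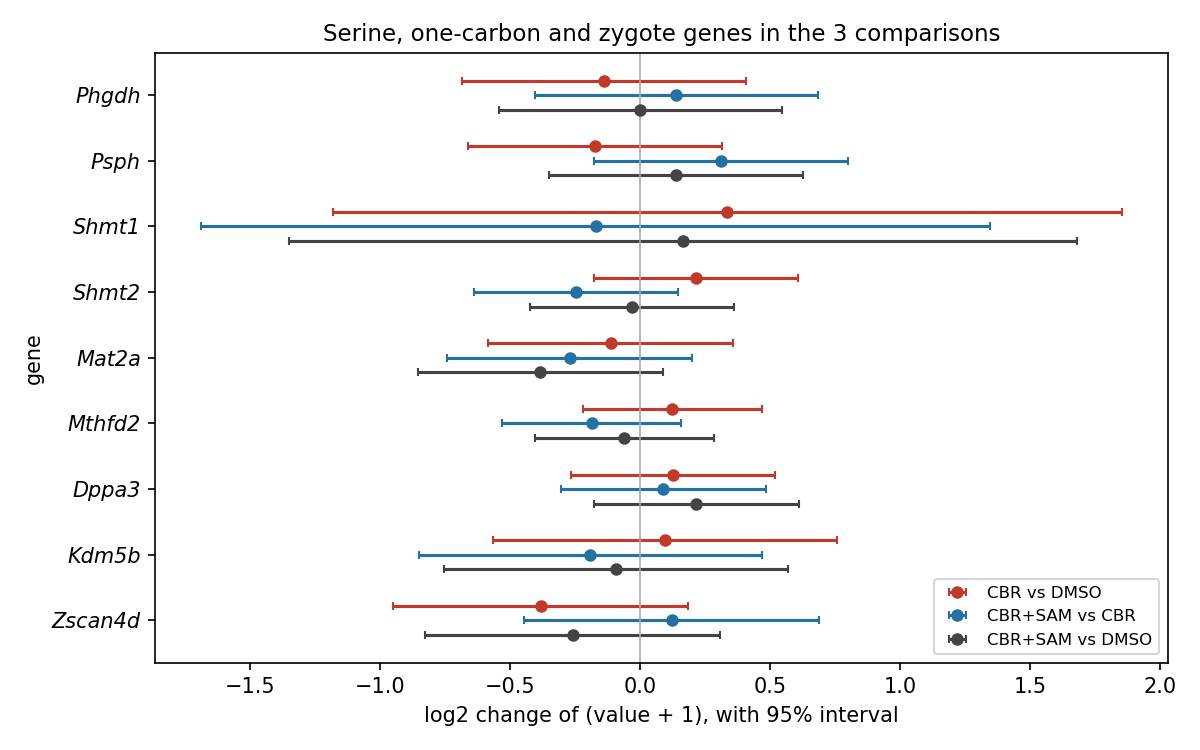
Log2 change of (value + 1) with its 95% interval from limma for 9 genes of serine, one-carbon and zygote biology, 1 colour per comparison. Every interval includes 0, for example -0.68 to 0.41 for Phgdh in CBR against DMSO.

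Genes of the fixed lists for genome activation were also examined, since the series is about minor genome activation. Their levels do not separate newly made transcripts from mRNA carried over from the oocyte. Zscan4d stood at 9.14 ± 2.44 with DMSO and 6.71 ± 1.13 with CBR, a log2 change of -0.38 (95% interval -0.95 to 0.19). Of the 27 genes of the 2-cell and minor activation list, 21 had lower means with CBR, with a mean log2 change of -0.13 (camera adjusted p = 0.272). The summed values of the list were 13970 and 14640 with DMSO and 15720 and 17320 with CBR. Obox1, 1 of the most abundant transcripts of these embryos, gave 5421 and 5608 of the DMSO sums and 6130 and 6723 of the CBR sums. The sums therefore reflect a few abundant members. Ubtfl1, the member with the smallest unadjusted p, stood at 0.411 ± 0.0415 with DMSO and 1.34 ± 0.145 with CBR, and the homeobox gene Obox2 at 3690 ± 86.7 and 4660 ± 71.2. The list of major activation genes, mostly nucleolar and ribosome biogenesis factors, was higher as a group, with positive changes in 22 of 33 and a mean of 0.10 (adjusted p = 0.0269, camera). With an estimated correlation between genes its adjusted p was 0.709, and the call was also lost without a filter on low values (0.105), with a mean of at least 10 (0.0718), and without DMSO replicate 1 (0.262), DMSO replicate 2 (0.0501) or CBR replicate 2 (0.288). Rrp9, a nucleolar processing factor, stood at 19.3 ± 0.145 with DMSO and 25.8 ± 0.701 with CBR, and Rrs1 at 4.74 ± 0.218 and 7.15 ± 0.408. Dppa3, which protects the maternal genome from demethylation, and the histone demethylase gene Kdm5b had intervals of -0.27 to 0.52 and -0.56 to 0.76.

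The housekeeping lists below passed at the preset correlation between genes, but not with an estimated one. Ribosomal protein genes were lower with CBR in 68 of 89, with a mean log2 change of -0.17 (adjusted p = 0.000256, camera), for example Rps6 at 40.7 ± 2.21 with DMSO and 29.3 ± 2.34 with CBR, and Rpl8 at 6.76 ± 0.399 and 4.46 ± 0.808. Their summed values did not separate the groups, at 6696 and 6756 with DMSO and 6807 and 6502 with CBR. Nuclear genes of the respiratory chain were lower in 61 of 77, with a mean of -0.14 (0.000399), for example Atp5g2 at 18.5 ± 1.02 and 10.9 ± 1.86. With an estimated correlation the adjusted p was 0.784 for both of these lists, and without DMSO replicate 2 it was 0.185 for ribosomal proteins and 0.368 for the respiratory chain.

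**Figure D3:**
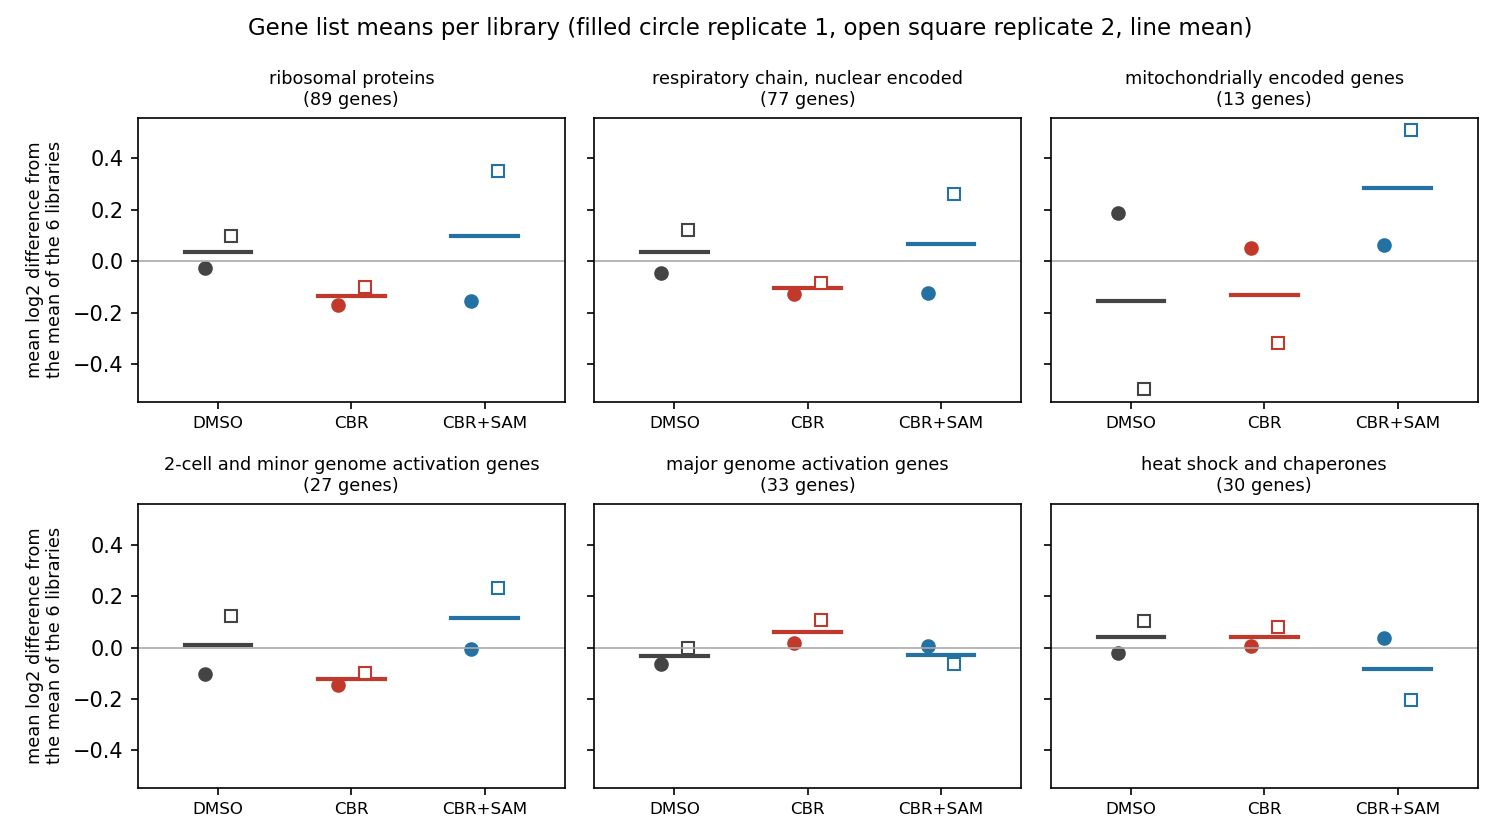
Mean over the genes of 6 lists of the log2 difference from the mean of all 6 libraries, with 1 point per library and a line at each group's mean. CBR+SAM replicate 2 stands apart in several lists, at 0.35 for ribosomal proteins where CBR+SAM replicate 1 is at -0.16, and at 0.51 for mitochondrially encoded genes where DMSO replicate 2 is at -0.50.

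The other lists did not pass in CBR against DMSO, by camera with Benjamini-Hochberg adjustment. Among chromatin and DNA lists the adjusted p was 0.254 for histone methyltransferases, 0.653 for histone demethylases, 0.351 for DNA methylation, 0.521 for histone variants and their chaperones, 0.787 for canonical histones and 0.273 for DNA damage response and repair, where 47 of 82 changes were positive. It was 0.787 for p53 targets, 0.92 for apoptosis, 0.325 for the integrated stress response, 0.787 for heat shock and chaperones, 0.976 for antioxidant genes and 0.254 for the cell cycle. Oocyte and maternal-effect genes (0.653) and maternal mRNA decay factors (0.673) were also not past it. The metabolic lists gave 0.92 for nucleotide synthesis, 0.273 for glycolysis and 0.162 for the tricarboxylic acid cycle, in which 17 of 27 changes were negative. Markers of cumulus (0.227), sperm (0.787) and oviduct cells (0.673) did not pass, and no blood cell gene was high enough to test.

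No single gene passed, and the 5 named on each side had the smallest unadjusted p-values among genes with a mean of at least 10 and groups that did not overlap, with predicted genes left out, some of which had smaller ones. The higher ones were Zfp236 (14.9 ± 0.804 with DMSO, 34.7 ± 6.64 with CBR), mt-Nd4l (804 ± 278 and 1550 ± 239), the chromatin remodeller gene Pbrm1 (34.0 ± 0.802 and 49.1 ± 1.33), Lbhd1 (10.2 ± 2.2 and 18.5 ± 1.1) and Tex14 (18.4 ± 0.121 and 26.9 ± 2.54). The lower ones were mt-Nd2 (1720 ± 645 and 775 ± 216), Rps6, the H3K36 demethylase gene Kdm2a (74.4 ± 2.73 and 51.1 ± 2.88), Qpct (14.6 ± 0.867 and 10.1 ± 0.141) and Atp5g2. In the mitochondrially encoded list (0.673) mt-Nd2 was lower and mt-Nd4l higher, each with an adjusted p of 0.037 by limma adjusted over the list alone, while 0 of its 13 genes passed over all genes. In the stress response list a second record of Ddit3 (ENSMUSG00000116429) was listed at 0 in both DMSO libraries and at 8.37 and 15.7 with CBR. That record overlaps the main Ddit3 gene, which stood at 46.9 and 46.3 with DMSO and 38.6 and 42.1 with CBR, so its reads are uncertain.

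The count of 0 called genes came from limma on all 6 libraries. At an unadjusted p under 0.05 there were 260 genes, 100 higher and 160 lower, where 612.5 would be reached by chance, and 33.0% of the genes had groups that did not overlap, against 33.3% by chance. That share was 27.5% in CBR+SAM against CBR and 24.5% in CBR+SAM against DMSO. Both chance values assume independent and interchangeable libraries. Libraries with the same replicate number resembled each other, so neither value measures chance exactly. The count of 260 was 169 without DMSO replicate 2, 541 and 538 without CBR+SAM replicate 1 or 2, and 534 with the 4 compared libraries alone, and it was 77 among genes with a mean of at least 10 and 882 without a filter. Simulated data of the same size recovered 22.4% of genes changed 2-fold and 70.3% of genes changed 4-fold, so a change of the former size could miss the adjusted threshold in most genes. The intervals of single genes say more. Over the 5939 genes with a mean of at least 10 the median half-width of the 95% interval was 0.434 log2. Fitted changes lay within 0.5 in 98.8% of them, and an interval of that width around such a change excludes a log2 change of 1. The fit on the 4 libraries compared alone called 1 gene, the processed pseudogene Gm6565, which is named after its values were seen. It stood at 87.6 and 85.0 with DMSO and 22.6 and 23.4 with CBR. In the CBR+SAM libraries, which that fit left out, it stood at 3.66 and 101, so it varied widely within a group.

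The comparison of CBR+SAM with CBR asked what supplying the methyl donor does to inhibited embryos. Without a group given SAM alone, it does not show whether such an effect depends on the inhibitor. Gadd45g stood at 0.97 ± 0.289 with CBR and at 7.07 ± 0.886 with CBR+SAM (mean ± SD, n = 2). Kdm2a stood at 51.1 ± 2.88 and 82.3 ± 17.7, Pbrm1 at 49.1 ± 1.33 and 34.9 ± 1.15, and Ehmt2 at 3.83 ± 0.303 and 3.06 ± 0.148. Only 1 of the 12249 genes passed the test, the processed pseudogene Gm16550, which was listed at 0 and 0.000873 in the CBR libraries and at 8.34 and 8.59 in the CBR+SAM libraries (adjusted p = 0.0098, limma).

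Gm16550 (ENSMUSG00000089967) occupies 126 bases on chromosome 1, from 165148824 to 165148949 in mm10, and is named here because it was the only call. Over 99.2% of its length it was identical to a transcript of Dnajc9, which stood at 124 and 133 with CBR and 127 and 106 with CBR+SAM, so the division of reads between the copies is uncertain. Its call was lost without a filter on low values (adjusted p = 0.172, limma), with a pseudocount of 0.1 (0.353), and without CBR replicate 1 (0.227), CBR replicate 2 (0.228) or CBR+SAM replicate 2 (0.157). It was not tested among genes with a mean of at least 10 or among protein-coding genes, where no gene was called, and over the settings that tested it the adjusted p ran from 0.00956 to 0.353. Gadd45g had a log2 change of 2.04 (SE 0.21), with adjusted p = 0.133 by limma over all genes and 0.000499 adjusted over the list alone. Counts at an unadjusted p under 0.05 were 212 higher and 166 lower. Without CBR+SAM replicate 1 the called genes were 9, Serpine2 among them, and the 378 at an unadjusted p under 0.05 became 2369, while they were 242 without CBR replicate 1, 141 with a mean of at least 10 and 1000 without a filter.

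5 of the 28 lists passed, and for each of them CBR+SAM replicate 2 decided the call. Genes of the 2-cell and minor activation list were higher with SAM in 22 of 27, with a mean log2 change of 0.24 (adjusted p = 0.0061, camera). Its adjusted p was 0.642 with an estimated correlation, 0.759 without CBR+SAM replicate 2, 0.0554 without CBR replicate 1 and 0.257 with a mean of at least 10. Among them Obox7 stood at 548 ± 96.8 with CBR and 737 ± 170 with CBR+SAM, Zscan4f at 1.65 ± 0.864 and 2.94 ± 1.07, and Rfpl4b at 0.106 ± 0.0823 and 0.761 ± 0.529. Ribosomal protein genes were higher in 82 of 89 (mean 0.23, adjusted p = 1.12e-06), nuclear respiratory chain genes in 66 of 77 (mean 0.17, 3.83e-05) and mitochondrially encoded genes in 11 of 13 (mean 0.42, 0.000479). The summed ribosomal protein values were 6807 and 6502 with CBR and 6258 and 8488 with CBR+SAM. Heat shock and chaperone genes were lower in 23 of 30 (mean -0.13, 0.0131), for example Hspb1 at 10.6 ± 0.674 and 6.63 ± 0.718 and the endoplasmic reticulum chaperone gene Hspa5 at 68.4 ± 2.97 and 50.2 ± 14.3. With an estimated correlation the adjusted p of each of these 4 lists was 0.642, too. Without CBR+SAM replicate 2, the library with the low Serpine2 value, it was 0.605 for mitochondrially encoded genes and 0.837 for heat shock, and the ribosomal and respiratory lists changed direction, with 0.837 each. The mitochondrially encoded and heat shock calls were also lost without CBR replicate 2 (0.367 each), and heat shock with a mean of at least 10 (0.132).

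The remaining 23 lists had adjusted p-values of 0.118 to 0.885 by camera, those of serine and glycine metabolism (0.553), DNA damage response (0.437) and histone methyltransferases (0.815) among them. In the mitochondrial list mt-Nd2 stood at 775 ± 216 with CBR and 2190 ± 89.2 with CBR+SAM, with an adjusted p of 0.0137 by limma adjusted over the list alone and 0.988 over all genes. mt-Cytb stood at 3020 ± 162 and 5540 ± 1990. The other genes named by the same rule, with predicted genes again left out, were on the higher side Bglap3 (8.53 ± 1.23 with CBR, 16.7 ± 1.84 with CBR+SAM), the actin-bundling gene Lcp1 (88.3 ± 8.27 and 138 ± 1.82) and Cisd3 (11.2 ± 0.735 and 17.8 ± 0.854). On the lower side they were the small GTPase gene Rac3 (14.0 ± 1.02 and 8.48 ± 0.113), the remodeller gene Chd4 (17.3 ± 1.32 and 10.1 ± 2.27), the autophagy gene Atg14 (88.1 ± 2 and 57.8 ± 12.3) and Spink2 (37.1 ± 3.11 and 22.0 ± 5.25). Mettl16, an RNA methyltransferase that controls Mat2a mRNA, stood at 8.5 ± 0.563 and 5.27 ± 0.638. Phgdh had a log2 change of 0.14 (95% interval -0.40 to 0.69).

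The comparison of CBR+SAM with DMSO showed what difference from the control was present with both compounds. Gadd45g stood at 7.15 ± 0.732 in DMSO embryos and 7.07 ± 0.886 in CBR+SAM embryos (mean ± SD, n = 2), a log2 change of -0.02. Ehmt2 stood at 1.56 ± 0.187 and 3.06 ± 0.148, and Zfp236 at 14.9 ± 0.804 and 24.5 ± 3.92. Lbhd1 stood at 10.2 ± 2.2 and 29.6 ± 8.37. Mitochondrially encoded genes were higher with CBR+SAM in 13 of 13, with a mean log2 change of 0.44 (adjusted p = 2.69e-07, camera). The adjusted p was 0.954 with an estimated correlation, 0.501 without DMSO replicate 2 and 0.086 without CBR+SAM replicate 2.

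Among the mitochondrial genes mt-Nd1 stood at 3870 ± 1210 with DMSO and 5590 ± 965 with CBR+SAM, and mt-Cytb at 4020 ± 598 and 5540 ± 1990. Heat shock and chaperone genes were lower in 23 of 30 (mean -0.13, adjusted p = 0.037, camera), with Hspa5 at 73.8 ± 6.75 and 50.2 ± 14.3. With an estimated correlation the adjusted p of heat shock was 0.954, and its call was also lost without DMSO replicate 2 (0.501), CBR+SAM replicate 2 (1), CBR replicate 1 (0.0641) or CBR replicate 2 (0.0634), with the replicate number as a block (0.0759), without a filter (0.102), with a mean of at least 10 (0.052) and with the length trend removed (0.0646). The remaining 26 lists had adjusted p-values of 0.299 to 0.957, with ribosomal proteins, minor activation genes and folate genes at 0.299, and no list had a member past the threshold adjusted over the list alone.

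Gm16550 was again the only gene past the threshold, listed at 0 in both DMSO libraries (adjusted p = 0.00979, limma), and its call was lost without any 1 library other than DMSO replicate 2, with adjusted p-values of up to 0.106, and with a pseudocount of 0.1 (0.322) or without a filter (0.172). At an unadjusted p under 0.05 there were 124 higher and 138 lower genes, and their total of 262 became 152 without DMSO replicate 2, 2044 and 401 without CBR+SAM replicate 1 or 2, 73 with a mean of at least 10 and 934 without a filter. Besides Zfp236 and Lbhd1, the higher genes named by that rule, none past the threshold, were Lcp1 (93.9 ± 11.9 with DMSO, 138 ± 1.82 with CBR+SAM), Dock10 (417 ± 58.3 and 844 ± 393) and Samd15 (45.2 ± 0.41 and 75.4 ± 25). The lower ones were Rac3 (12.7 ± 0.0212 and 8.48 ± 0.113), Chd4 (15.6 ± 0.515 and 10.1 ± 2.27), Fgd6 (24.4 ± 3.27 and 16.6 ± 1.26), Dmap1 (16.0 ± 2.41 and 10.8 ± 0.473) and Zfp24 (16.9 ± 0.0236 and 12.1 ± 0.37). Mat2a stood at 46.0 ± 0.685 and 35.5 ± 8.05, and Dppa3 at 13600 ± 46.7 and 15900 ± 2770.

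Whether SAM brought inhibited embryos back toward the control was to be read from the genes called in CBR against DMSO, of which there were 0, so no recovery could be computed. Gadd45g and mt-Nd2 were among the 15 genes with an unadjusted p under 0.01 in opposite directions in CBR against DMSO and CBR+SAM against CBR, where simulated data without any effect gave a mean of 29.9 and at most 42. Across genes, which are not independent replicates, the log2 changes of CBR and of CBR+SAM against DMSO correlated at 0.37, where 0.497 was simulated with no effect from the shared DMSO libraries. With each library left out, against a simulation of the same libraries added after the data were seen, it was 0.617 against 0.667 and 0.603 against 0.665 without DMSO replicate 1 or 2, 0.292 against 0.408 and 0.286 against 0.407 without CBR replicate 1 or 2, and 0.166 against 0.404 and 0.398 against 0.411 without CBR+SAM replicate 1 or 2. Their covariance was 0.0251 against 0.0529 in the simulation. The simulation gave every library of a gene the same variance and no shared replicate numbers, and its CBR against DMSO changes had a variance of 0.106 against 0.0646 observed, so none of these values measures chance exactly. The 2 DMSO libraries were not split, since each part would keep 1 library, so the part that comes from the shared control remained in these values.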

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

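Precision weights, protein-coding genes only and the length trend were added after seeing the data; the other alternatives were fixed before the data were examined. The cause of the differences was not tested, except where fewer genes or libraries were used. For CBR against DMSO the count of called genes was 0 in every setting but the 4 libraries compared alone (1, Gm6565) and the leave-one-out fits (0 to 2, with 2 without DMSO replicate 2, Gm8203 and Iglj3). For CBR+SAM against CBR and against DMSO the count of 1 became 0 without a filter, with a mean of at least 10, with a pseudocount of 0.1 and with protein-coding genes only, and ran from 0 to 9 and from 0 to 3 with 1 library left out, where a lone library is assumed to vary like the other groups. Lists past the threshold in CBR against DMSO went from 3 to 0 with an estimated correlation and ran from 1 to 4 with libraries left out. In CBR+SAM against CBR they went from 5 to 3 with a mean of at least 10 and to 0 with an estimated correlation, and ran from 0 to 6. In CBR+SAM against DMSO the 2 became 1 without a filter, with a mean of at least 10, with the replicate block, with the length trend removed and with the compared libraries alone, and 0 with an estimated correlation, and ran from 1 to 5. Without CBR+SAM replicate 2 the ribosomal and respiratory lists reversed in CBR+SAM against CBR (adjusted p 0.837 each, camera), and without CBR+SAM replicate 1 they had 7.61e-13 and 1.01e-10. The correlation of 0.37 was 0.274 with a mean of at least 10 and 0.417 with a pseudocount of 0.1, and 0.166 to 0.617 with libraries left out. All 10 list calls were kept with either other scaling, which moved the median gene by at most 0.08 log2, and with a pseudocount of 0.1. Since camera compares a list with the other genes, a scaling shared by all genes of a library could change these calls little. Unadjusted p-values of fry for the 10 list calls ran from 0.111 to 0.492. Its smallest p for 1 direction was 0.00483, for apoptosis in CBR+SAM against CBR. For changes in either direction the list of DNA methylation genes, which holds Gadd45g, had 7.65e-05 in CBR against DMSO and 0.000127 in CBR+SAM against CBR (fry, unadjusted). With the replicate number as a block the called genes were 0, 1 and 1, and those at an unadjusted p under 0.05 rose to 357, 554 and 340; the block ended only the heat shock call in CBR+SAM against DMSO (0.0759). Deviations of same-numbered libraries correlated at 0.392, 0.218 and 0.091, and 6 of 6 libraries correlated best with a library of their own number, a hint from the data and not from the design. The DESeq2 Wald test, limma-voom, edgeR's TMM factors and a stricter threshold for recovery were not run, since they need counts or called genes. At 21 to 27.0 M estimated reads, Gadd45g in a CBR library rests on about 17 to 23.1 reads.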

Other observations

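The tests of copies for Gadd45g and Gm16550 and of Gadd45g over all genes were written before their results were seen, and the other tests below afterwards; a copy test for mt-Nd2 was dropped as a test after its result was seen, its values are given here, and the Ddit3 and Gm16550 tests were joined under 1 pattern after both had run. Among genes with opposite changes in CBR against DMSO and CBR+SAM against CBR, chosen after their values were seen, Gm28438 on chromosome 1 stood at 869 ± 148 with DMSO, 404 ± 46.9 with CBR and 1330 ± 361 with CBR+SAM (mean ± SD, n = 2). Its transcript was matched over 100% of its length by mt-Nd3 at 99.7% identity, and mt-Nd3 itself stood at 1050 ± 458, 715 ± 99.1 and 1390 ± 675. For mt-Nd2, the closest other transcript was that of Gm13339, which covered 49.1% of it and lay between 0 and 0.624 in the 6 libraries. Tmigd3 stood at 1.52 and 0.591 with DMSO, 3.09 ± 0.843 with CBR and 0.834 ± 0.0506 with CBR+SAM.

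Gadd45g was low in both CBR libraries and back at the control level in both CBR+SAM libraries. Counting error alone is argued against, since about 40 estimated reads in the CBR libraries against 590 in the 4 others gave a ratio per sequenced read with an upper 95% bound of 0.186 (exact binomial interval). A near-identical copy is argued against as well, since another gene's transcript covered 0% of it at 90% identity or more. Chance among 12249 genes stays open, because the adjusted p of the CBR libraries against the mean of the other groups was 0.0981 by limma. An effect of the inhibitor that SAM reverses may account for the pattern too, as a hypothesis that 2 libraries per group leave untested. No group received SAM alone, so a reversal could not be told apart from a separate effect of SAM.

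Some gene records were at or near 0 in some groups and at a level in another, and a division of reads between similar records may account for them. The second Ddit3 record was at 8.37 and 15.7 with CBR and at 0 with DMSO, yet the sum of both Ddit3 records had a log2 change of 0.16 (95% interval -0.37 to 0.68), so the locus as a whole showed no detectable change. Gm16550, the only called gene with CBR+SAM, was identical over 99.2% of its length to a transcript of Dnajc9, a gene at more than 100 in every library, and its values of 8.34 and 8.59 corresponded to about 13.1 and 15.7 reads. A sequence difference or real transcription of the pseudogene was not tested.

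Ribosomal protein genes were lower with CBR than with DMSO and higher with CBR+SAM than with CBR at the preset correlation between genes, but not with an estimated correlation (adjusted p of 0.784 and 0.642, camera), and their summed values overlapped between the groups in both comparisons, so the pattern itself is uncertain. A transcript length trend as the whole cause of the calls at the preset correlation is argued against. With the trend removed, the larger adjusted p of the 2 comparisons was 0.00147 (camera, preset correlation). With an estimated correlation there was no call for this test to explain. The difference between CBR+SAM and CBR rested on 1 library, CBR+SAM replicate 2, at 0.353 in the list mean. CBR+SAM replicate 1 was at -0.155, between the CBR libraries at -0.17 and -0.099. Without CBR+SAM replicate 2 that call was lost and the direction turned. The call in CBR against DMSO was lost without DMSO replicate 2. A treatment effect on these genes, and reads divided among their many pseudogenes, remain open and untested.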
